A study of Mus musculus with 8 samples.

How the data were processed

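The series compared the caudal part of the urogenital ridge of Sox11 knockout and wild type mouse embryos at embryonic day 10.75. RNA was taken in 4 independent replicates per genotype from mice of mixed genetic background, treated to reduce ribosomal RNA, amplified with an Affymetrix whole-transcript kit and labelled with biotin, per the labels' protocols. Whether a replicate was 1 embryo or a pool is not given in the sources used here.

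The deposited table holds 1 log2 signal for each of 27478 probe sets on each of the 8 arrays. The authors made these values with RMA, a method that corrects background, quantile-normalizes the arrays and sums up the probes of a probe set, and Partek is named beside it, per the submitters' processing notes. Their versions, the settings and any filter are not given in the sources used here. That the scale is log2 was read from the deposited values, which ran from 4.30 to 14.62 with array medians between 7.29 and 7.31. RMA forces the arrays to nearly the same distribution, so a shift of all transcripts together could not be seen, and signal near the lower end of the range understates differences. Arrays carry no count of molecules, and the small number of arrays is 1 limit on the precision here. The median SD within a genotype was 0.12 on the log2 scale.

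Probe sets were named from the platform's annotation. Of them, 21103 had exactly 1 gene symbol, 1531 had several and 4844 had no symbol in the annotation used here. Symbols were updated through the gene identifiers of RefSeq's annotation of GRCm38.p6, where 80 symbols had no entry and 0 changed name. The build used by the authors is not given in the sources used here, so no position is printed and the annotation served only for names and for which genes neighbour each other. For each gene the probe set with the highest mean over the 8 arrays was kept, which gave 19356 genes, 956 of them with more than 1 probe set. No gene was removed for a low level.

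Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, genotype as the only term, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. Each change is knockout minus wild type on the log2 scale. Gene lists were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over 40 lists, and again with an estimated correlation, on ranks, and with fry, which asks whether the genes of a list move on balance in 1 direction. The lists held genes of the kidney primordium, of signalling pathways, of cell states, of other cell types that a dissected ridge may hold, and of RNA classes that track sample quality. They named 529 genes besides those chosen by symbol pattern, of which 503 were measured and 26 were not used here. The percentage of genes near Sox11 with an unadjusted p under 0.05 was compared with that of other genes by Fisher's exact test, over the genes other than Sox11 that have a position in the RefSeq table. Figures were drawn with matplotlib 3.10.9.

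The design, the lists, the alternatives and the rule for the genes to be named were fixed before the data were examined. The rule took Sox11, Sox4 and Sox12, the 10 largest rises and the 10 largest falls among genes past the threshold other than predicted genes and clones, 17 genes of kidney development whatever their result, and the members with the lowest p of the lists (up to 4 for kidney lists and lists past the threshold, up to 3 for lists of other cells, of states, of RNA classes and of embryo sex). From these the text names 75. Genes named outside the rule are said to be chosen after their values were seen.

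The alternatives were median centring, a further quantile normalization, filters at the 25th percentile and at the median of level, a test of every probe set, the mean of a gene's probe sets, eBayes with trend and robust, a linear model per gene without moderation, array weights, the replicate number as a block, the Y-linked signal of each array as a covariate, other thresholds, other windows around Sox11, and leaving out each array in turn. The labels number the replicates 1 to 4 in both genotypes without saying that a number marks a shared litter or day. The analysis was tested on simulated data with the same 19356 genes and 4 against 4 arrays. It recovered 64% of 100 genes changed by 0.5 on the log2 scale and 93% of 100 changed by 1, with 8 false calls among 165. A list of 19 genes shifted by 0.3 was recovered, and 0 of the 39 other lists were called by camera. The simulated genes varied independently of each other, so this does not show how often camera calls lists of correlated genes.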

Results

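Gene expression was measured on 8 arrays, each hybridised with RNA from the caudal end of the urogenital ridge of mouse embryos at E10.75. At this stage the ureteric bud begins to grow out of the nephric duct towards the metanephric mesenchyme, and the kidney forms from both. There were 4 wild type and 4 Sox11 knockout replicates. The 19356 genes correlated between arrays at 0.987 to 0.995 (Pearson's r across genes, which are not independent replicates). The first principal component held 27.4% of the variance and parted the genotypes, with the wild type arrays between -15.7 and -3.50 and the knockout arrays between 5.23 and 16.6. The Y-linked genes Eif2s3y and Kdm5d gave signal in 1 of the 4 wild type arrays (replicate 1) and in 2 of the 4 knockout arrays (replicates 3 and 4), so the sexes were not evenly spread over the genotypes.

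Sox11 encodes a transcription factor of the SoxC group and is the gene targeted in these embryos. Its log2 signal (probe set 10399725) was 11.79 ± 0.06 (SD, n = 4) in wild type and 9.10 ± 0.13 (SD, n = 4) in knockout ridges, and every knockout array lay below every wild type array. Sox11 thus fell by 2.69 on the log2 scale (SE 0.08), which is 6.44-fold lower, with a limma adjusted p of 6.36e-08. The related factors Sox4 and Sox12 differed by 0.20 (SE 0.10, limma adjusted p = 0.354) and 0.02 (SE 0.07, limma adjusted p = 0.921) and did not pass the threshold. Over the 3 SoxC genes the median change was 0.02 and the mean -0.82, so median and mean differed in sign (camera adjusted p = 0.167). Of 6 genes reported as SoxC targets, all but Tead2 are also in the list of neurons. Dcx, a microtubule-binding protein of young neurons, passed the threshold over all genes, and 3 passed when adjusted over these 6 alone (Dcx, Tead2 and Stmn2). As a list these 6 had a camera adjusted p of 0.121, which was 0.0406 without wild type replicate 3, 0.0380 without knockout replicate 3 and 0.0392 with the Y-linked signal as a covariate. Whether the Sox11 probes lie in the deleted part of the gene is not given in the sources used here, so the signal left in the knockout has no reading.

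In the knockout ridges 209 genes were lower and 70 were higher than in wild type. After Sox11 the largest falls were in Car14, a membrane-bound carbonic anhydrase, at -1.73 (SE 0.14), and in Nlrp5-ps, a pseudogene, at -1.59 (SE 0.19). Then came 5 protocadherin beta genes, which encode neural cell adhesion proteins (Pcdhb21 -1.42, Pcdhb18 -1.34, Pcdhb17 -1.29, Pcdhb20 -1.21 and Pcdhb19 -1.20), the organic anion transporter family gene Slco5a1 at -1.30 and Dpysl5, a collapsin response mediator of growing neurites, at -1.20. The largest rises were in Col8a1, a short-chain collagen, at 1.12 (SE 0.23), the phosphatase gene Ublcp1 at 1.03 (SE 0.12) and Aldh1a3, an enzyme that makes retinoic acid, at 0.98 (SE 0.09). Sult5a1 (0.94), the adhesion gene Cntn1 (0.93), Hamp, which encodes the iron hormone hepcidin (0.90), the potassium channel gene Kcnh5 (0.88), the receptor tyrosine kinase gene Ros1 (0.76), Wfdc15b (0.76) and Zfp36l1, an mRNA decay factor (0.72), rose as well.

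The 279 genes passed limma's test at an adjusted p under 0.05, and in all of them the 4 knockout arrays lay to 1 side of the 4 wild type arrays. Over all genes this held for 2035, or 10.5%, where chance gives 2.86%. Changes were mostly small: 77 genes were at least 1.5-fold lower and 26 at least 1.5-fold higher, and 21 and 2 reached 2-fold. Among the 10 largest falls none lost its call when any 1 array was left out, whereas among the 10 largest rises only Aldh1a3, Ublcp1 and Kcnh5 kept theirs throughout. Col8a1 missed the threshold without each array but wild type replicate 1 (limma adjusted p up to 0.123), and Cntn1 without each array but knockout replicate 2 (up to 0.114). Ros1 was lost without wild type replicates 1 and 4 and each knockout array (up to 0.101), Sult5a1 without wild type replicates 2, 3 and 4 and knockout replicates 1, 2 and 4 (up to 0.0684). Hamp was lost without wild type replicates 2 and 4 and knockout replicates 1, 3 and 4 (up to 0.0963). Wfdc15b and Zfp36l1 were lost without wild type replicates 1, 2 and 4 and knockout replicates 1, 3 and 4 (up to 0.0967 and 0.131). On all arrays, the Y-linked signal as a covariate ended the calls of Col8a1, Hamp, Ros1, Wfdc15b and Zfp36l1 (limma adjusted p up to 0.0797), and the replicate block that of Hamp (0.0689). A test of every probe set ended those of Cntn1, Col8a1, Wfdc15b and Zfp36l1 (limma adjusted p up to 0.0644), a trended and robust moderation those of Col8a1 and Zfp36l1 (0.0666 and 0.0531), and a model without moderation those of each of the 10 rises but Aldh1a3 (up to 0.172) and of Nlrp5-ps, Pcdhb21, Pcdhb17, Pcdhb20 and Pcdhb19 (up to 0.0732). The count of 279 was 182 without wild type replicate 1, 107 without replicate 2 and 173 without replicate 3, and 117, 184, 145 and 107 without knockout replicates 1, 2, 3 and 4, while a linear model without moderation called 55, the replicate number as a block left 166 and the Y-linked signal as a covariate 151.

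**Figure D1:**
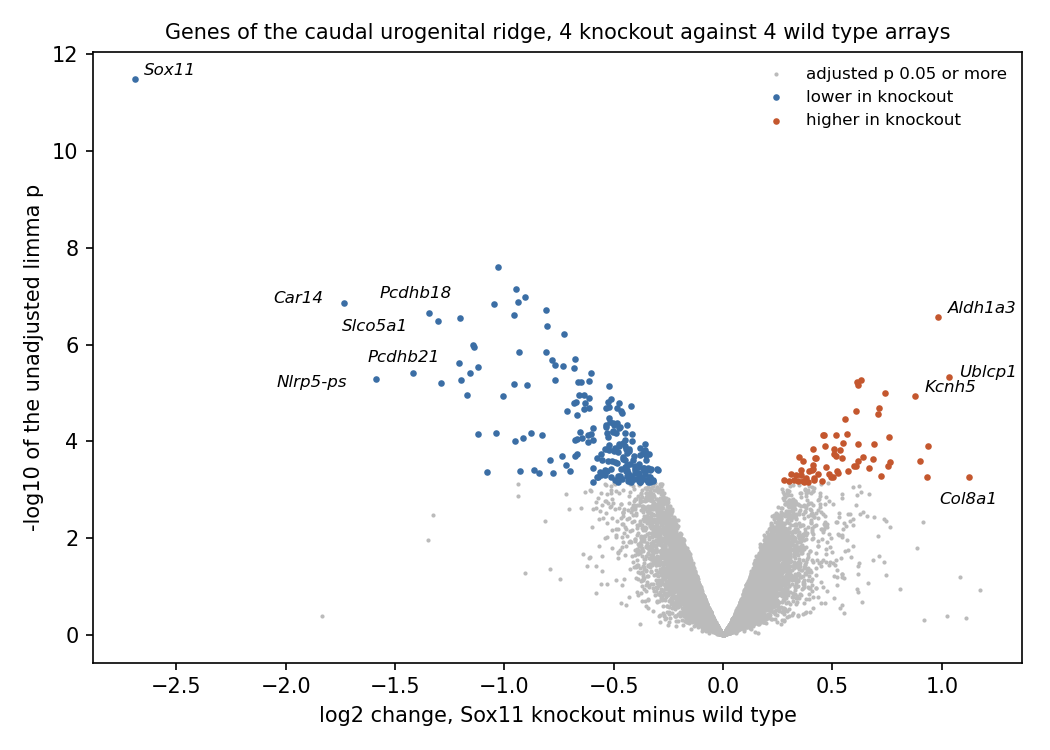
Each point is 1 of 19356 genes, with the log2 change (knockout minus wild type) on the horizontal axis and minus the log10 of the unadjusted limma p on the vertical axis. Blue points are the 209 genes lower and orange points the 70 genes higher in knockout at an adjusted p under 0.05, and Sox11 stands apart at -2.69.

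Protocadherin beta genes, a group chosen after its values were seen, had 12 of 21 measured members lower past limma's threshold over all genes. All 21 lay below 0, with changes from -1.42 to -0.20 and a median of -0.68. Every member stayed below 0 under both further normalizations. Among the 14 members above the 25th percentile of level 11 passed, and their median was -1.08. Without moderation 1 member passed, and 10 to 13 passed when 1 array was left out. None of the 21 lay above the median level of all genes. Members of this family have similar sequences, so probes made for 1 of them may also read others, and single values are uncertain for that reason. The same holds for Nlrp5-ps and its parent gene Nlrp5 (-0.67, limma adjusted p = 0.0252) and for Hamp and Hamp2 (0.06, limma adjusted p = 0.857), where Nlrp5 and Hamp2 were also chosen after their values were seen. Nlrp5 missed the threshold without wild type replicates 2 and 4 and knockout replicates 1, 3 and 4 (limma adjusted p up to 0.0784), and also without moderation.

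The kidney genes asked whether loss of Sox11 changed the duct that forms the ureteric bud or the mesenchyme that attracts it. Ret, the receptor on the duct through which GDNF drives budding, rose from 9.66 ± 0.06 to 10.07 ± 0.10 (SD, n = 4 each), a change of 0.41 (SE 0.07) or 1.33-fold. Etv5, a transcription factor induced by RET signalling, fell by 0.40 on the log2 scale (SE 0.08), and its relative Etv4 was at -0.54 (SE 0.14) without passing. Six2, a transcription factor of nephron progenitors, fell by 0.48 on the log2 scale (SE 0.10), from 10.45 ± 0.16 to 9.97 ± 0.15 (SD, n = 4 each). Osr2, expressed in mesonephric mesenchyme, fell by 0.49 on the log2 scale (SE 0.10). The limma adjusted p was 0.0220 for Ret, 0.0368 for Etv5, 0.0437 for Six2, 0.0466 for Osr2 and 0.0960 for Etv4.

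The nephric duct and ureteric bud list rose, by a median of 0.16 with 21 of 27 measured genes above 0 (camera adjusted p = 0.00289). With an estimated correlation its adjusted p was 0.50. Over all genes 1 member rose (Ret), 1 fell (Etv5) and 25 did not pass. Adjusted over the list alone, 5 were higher and 2 lower, and the higher ones included Gata3 (0.25), Lhx1 (0.42) and Calb1 (0.63), which mark the duct epithelium and had limma adjusted p-values over all genes of 0.0845, 0.0577 and 0.0624. In the metanephric mesenchyme and nephron progenitor list Six2 fell and 23 of 24 genes did not pass, while adjusted over the list alone 3 were lower (Six2, Eya1 and Meox1). Eya1, which acts upstream of Gdnf, was at -0.28 (SE 0.06, limma adjusted p = 0.0609). Meox1, which is also in the list of somite genes, was at -0.94 (SE 0.20, limma adjusted p = 0.0517). The metanephric mesenchyme list had a median of -0.02 and a camera adjusted p of 0.0781. That p was 0.0204 without wild type replicate 2, 0.0438 without knockout replicate 3 and 0.0392 with the Y-linked signal as a covariate. In the list of GDNF/RET signalling and its targets Ret rose, Etv5 fell and 15 of 17 did not pass, against 1 higher and 3 lower adjusted over the list alone (Etv4, Etv5 and Myb, the last at -0.51), with a camera adjusted p of 0.118. Of the genes that start or limit budding, Gdnf (-0.06), Gfra1 (0.17), Wnt11 (0.01), Robo2 (-0.03), Grem1 (0.16), Bmp4 (0.09) and Wnt9b (0.15) had limma adjusted p-values between 0.470 and 0.939. Sall1 (-0.21), Pax2 (-0.20), Osr1 (0.12) and Tead2 (-0.28) had 0.243, 0.412, 0.604 and 0.0804.

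Other kidney lists did not pass. Stromal genes, among them Foxd1 at -0.63 (limma adjusted p = 0.0633), had a camera adjusted p of 0.749. Posterior Hox genes, among them Hoxd12 at -0.56 and Hoxb9 at -0.34 (limma adjusted p = 0.0633 and 0.106), had 0.270, and trunk Hox genes 0.749. Genes of mesonephric tubules and nephron differentiation, Osr2 among them, had 0.780, and genes of human congenital kidney anomalies 0.999, with Ret higher and Six2 lower over all genes and a median of 0.0110 against a mean of -0.00619. In the same arrays erythroid genes were lower by a median of 0.20, and ribosomal protein and muscle genes were higher by a median of 0.10 and 0.13. Ret lost its call without wild type replicates 2 and 3 and knockout replicates 1, 2 and 3 (limma adjusted p up to 0.0764), Etv5 and Six2 without each array but wild type replicate 1 (up to 0.101 and 0.122), and Osr2 without each array but wild type replicate 4 (up to 0.131). On all arrays, Etv5, Six2 and Osr2 missed the threshold with the Y-linked signal as a covariate (limma adjusted p = 0.0686, 0.0797 and 0.0814) and after a further quantile normalization (0.0657, 0.0610 and 0.0546) and when every probe set was tested (0.0526, 0.0636 and 0.0659). Etv5 missed it with the mean of its probe sets (limma adjusted p = 0.0801), Etv5 and Osr2 with the replicate block (0.0764 and 0.0755), and Ret, Etv5, Six2 and Osr2 without moderation (0.0692, 0.0979, 0.134 and 0.141). Gata3, Lhx1, Calb1, Eya1, Meox1, Foxd1, Myb and Hoxd12 passed under at least 1 alternative on all arrays (limma adjusted p from 0.0168 for Eya1 to 0.0453 for Lhx1 at the lowest). Etv4 passed without wild type replicate 2 (limma adjusted p = 0.0429), Calb1 without wild type replicate 3 (0.0220), Foxd1 without wild type replicate 1 or knockout replicate 3 (0.0179 to 0.0474) and Meox1 without wild type replicate 4 or knockout replicate 3 (0.0162 to 0.0486).

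**Figure D2:**
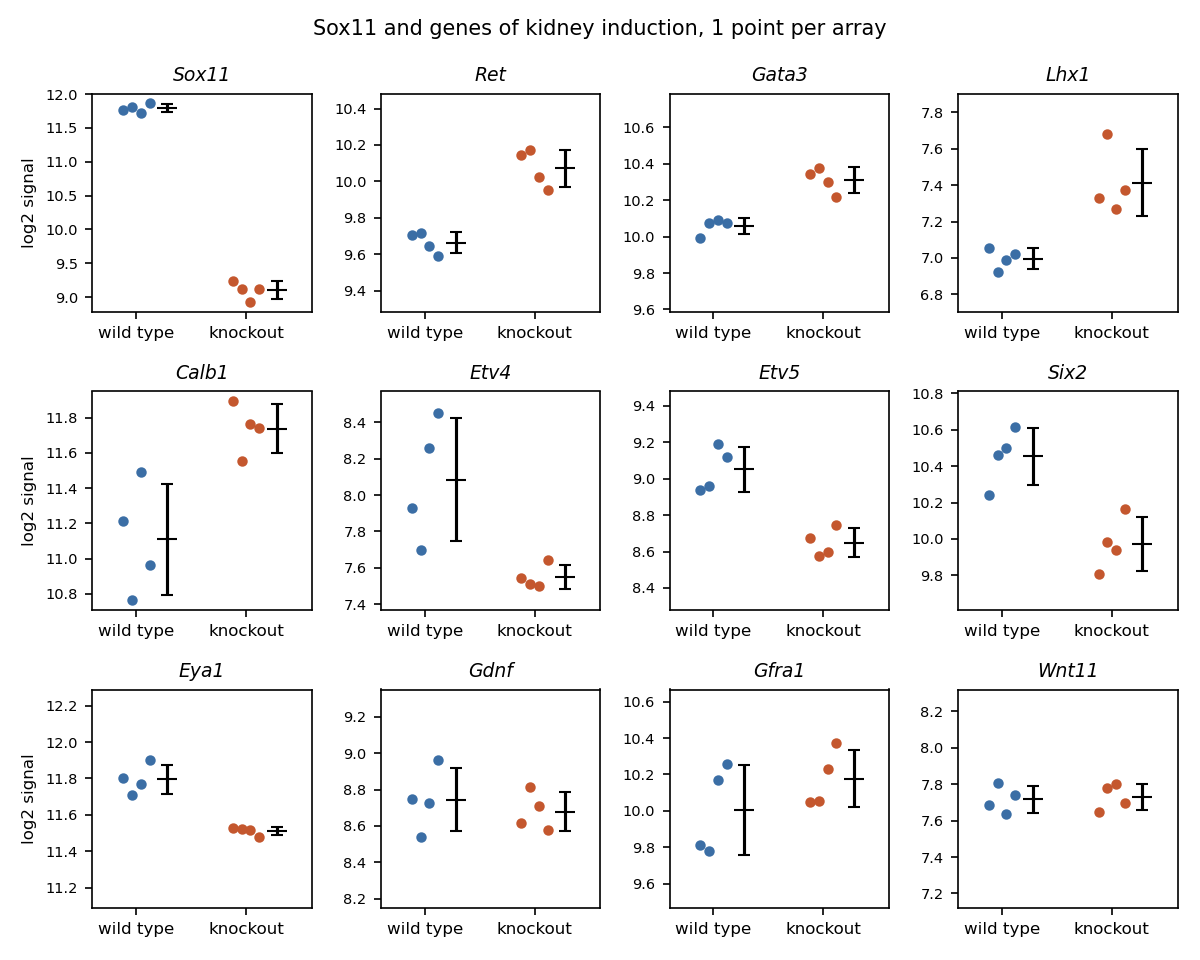
Each panel shows the log2 signal of 1 gene on the vertical axis, with 1 point per array (4 wild type in blue, 4 knockout in orange) and the mean with SD as a bar beside them. Sox11, Etv5 and Six2 were lower and Ret higher in knockout past the threshold, whereas Gdnf, Gfra1 and Wnt11 overlapped between genotypes.

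Among pathway and cell state lists, the FGF/ERK list fell, by a median of -0.20 with 12 of 13 below 0 (camera adjusted p = 7.56e-04). It holds an FGF ligand gene and an FGF receptor gene beside targets, and shares Etv4 and Etv5, among others, with the GDNF/RET list. With an estimated correlation the adjusted p was 0.50. Dusp4, an ERK phosphatase, fell by 0.86 on the log2 scale (SE 0.17, limma adjusted p = 0.0379), Etv5 fell as above and 11 did not pass, while 4 were lower adjusted over the list alone (also Etv4 and Il17rd). Genes of DNA replication and S phase fell by a median of -0.09, with 18 of 21 below 0 (camera adjusted p = 0.00289), and had an adjusted p of 0.638 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, fell by 0.77 on the log2 scale (SE 0.08, limma adjusted p = 0.00220) and Chaf1b, a histone chaperone subunit, by 0.36 (SE 0.06, limma adjusted p = 0.0254), and the same 2 passed adjusted over the list alone. Mitosis genes had a camera adjusted p of 0.931. The YAP/TEAD list, which holds the TEAD factor genes themselves beside targets, fell by a median of -0.14, with 10 of 12 below 0 (camera adjusted p = 0.0195). It had an adjusted p of 0.50 with an estimated correlation. Of these 12 genes limma called 0 over all genes, 4 were lower at an unadjusted p under 0.05, and 2 were lower adjusted over the list alone (Ajuba at -0.39 and the TEAD factor gene Tead2 at -0.28). Ccn1 and Amotl2 were at -0.28 and -0.27.

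WNT, retinoic acid, hedgehog, BMP and Notch target lists had camera adjusted p-values of 0.143, 0.270, 0.548, 0.926 and 0.999. Over all genes limma called 1 WNT target higher and 1 lower, and 1 retinoic acid target lower. Lists of p53 targets, unfolded protein response, oxidative phosphorylation, hypoxia and immediate early genes had 0.548, 0.548, 0.751, 0.999 and 0.999, and the hypoxia list had a median of 0.00309 and a mean of -0.00365, which differ in sign. Zmat3, a p53 target, fell by 0.35 on the log2 scale (limma adjusted p = 0.0255). Rrm2 also lies near Sox11 in the genome. The YAP/TEAD list had a camera adjusted p of 0.0947 without wild type replicate 2, 0.0575 after a further quantile normalization, 0.0792 with genes above the 25th percentile of level and 0.156 with genes above the median level. WNT targets, which lay higher in knockout, had 0.0393 without wild type replicate 3 and 0.0497 with genes above the median level. Dusp4 missed the threshold without each array but wild type replicates 1 and 4 (limma adjusted p up to 0.121), Chaf1b without wild type replicates 1, 2 and 3 and knockout replicates 1 and 4 (up to 0.0881), and Zmat3 without each array but wild type replicates 1 and 4 (up to 0.0930). On all arrays, Dusp4, Chaf1b and Zmat3 missed it with the replicate block (limma adjusted p = 0.0741, 0.0785 and 0.0921) and with the Y-linked signal as a covariate (0.0662, 0.0522 and 0.0528), and Dusp4 without moderation (0.152) and when every probe set was tested (0.0576). Of the 40 lists 8 passed camera and 0 passed with an estimated correlation, where the lowest adjusted p was 0.118, and 12 of the 35 splits of the 8 arrays into 4 and 4 gave at least 8 lists.

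**Figure D3:**
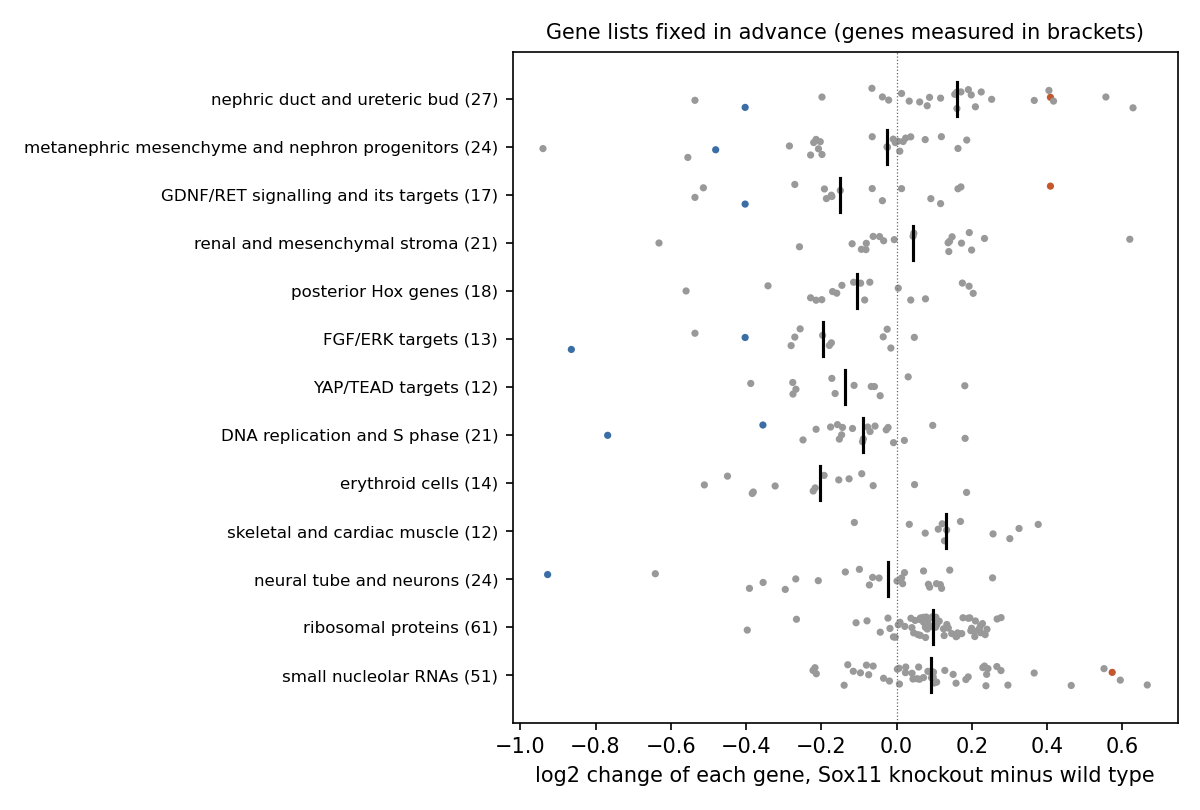
Each point is 1 gene of a list, placed by its log2 change (knockout minus wild type), with the median of the list as a black bar and the number of genes measured in brackets. Blue and orange points passed limma's test over all genes, and among the lists drawn here the medians ran from -0.20 in erythroid genes and FGF/ERK targets to 0.16 in nephric duct genes.

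Markers of other cells in the dissected ridge changed in a few lists. Erythroid genes fell by a median of -0.20, with 12 of 14 below 0 (camera adjusted p = 0.00650), and had an adjusted p of 0.686 with an estimated correlation. Limma called 0 of the 14 over all genes, 5 were lower at an unadjusted p under 0.05, and the blood group genes Rhd (-0.51) and Rhag (-0.45) were lower adjusted over the list alone, with Epb42 at -0.38. Muscle genes rose by a median of 0.13, with 11 of 12 above 0 (camera adjusted p = 0.0116), and had an adjusted p of 0.540 with an estimated correlation. Limma called 0 of the 12 over all genes, 4 were higher at an unadjusted p under 0.05, and Des, the intermediate filament gene of muscle, at 0.38 was higher adjusted over the list alone, with Myh7 at 0.33. Erythroid genes had a camera adjusted p of 0.0601 without wild type replicate 3 and 0.497 with genes above the median level, and muscle genes 0.0846 without wild type replicate 4 and 0.173 without knockout replicate 1.

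Lists of neurons, somites, gonad primordium and neural crest did not pass (camera adjusted p = 0.548, 0.926, 0.749 and 0.270), but single members did. Dcx fell by 0.93 on the log2 scale (SE 0.18, limma adjusted p = 0.0384), while the neuronal genes Stmn2 (-0.64) and Elavl4 (-0.30) had limma adjusted p-values of 0.213 and 0.173. In the somite list the homeobox genes Uncx and Meox2 fell by 0.88 and 0.50 on the log2 scale (limma adjusted p = 0.0148 and 0.0117), and Meox2 also lies near Sox11. Adjusted over the somite list alone, 3 were lower (Uncx, Meox2 and Meox1) and 1 was higher. That list had a median of 0.08 and a mean of -0.08, which differ in sign. Its test pointed upward, but downward with genes above the median level (camera adjusted p = 7.01e-04). In the gonad list Cbx2, a Polycomb gene needed for gonad development, fell by 0.48 on the log2 scale (SE 0.07, limma adjusted p = 0.00648). In the neural crest list Erbb3, a neuregulin receptor, rose by 0.36 (SE 0.07, limma adjusted p = 0.0417). Endothelial genes (camera adjusted p = 0.352), hepatocyte, germ cell and hindgut genes (0.548 each), leukocyte genes (0.749) and limb and body wall genes (0.751) did not pass. Without wild type replicate 2 endothelial and neural crest genes had camera adjusted p-values of 0.0204 and 0.0436, and with genes above the median level 0.0441 and 0.00984. Dcx was lost without each array but knockout replicate 3 (limma adjusted p up to 0.113), Erbb3 without any 1 of the 8 arrays (up to 0.113) and Uncx without knockout replicate 1 (0.0505), while Stmn2 passed without wild type replicate 3 (0.0449). On all arrays, Dcx and Erbb3 missed the threshold with the Y-linked signal as a covariate (limma adjusted p = 0.0508 and 0.0662), Erbb3 with the replicate block (0.0633), and Dcx, Erbb3, Uncx and Meox2 without moderation (0.155, 0.0874, 0.109 and 0.0646), and Dcx and Erbb3 when every probe set was tested (0.0581 and 0.0603).

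Genes of RNA classes that track sample quality were also compared. Ribosomal protein genes rose by a median of 0.10, with 52 of 61 above 0 (camera adjusted p = 3.41e-05), and had an adjusted p of 0.118 with an estimated correlation. Limma called 0 of the 61 over all genes and 0 adjusted over the list alone, while at an unadjusted p under 0.05, 12 were higher (Rps12 at 0.22 and Rpl19 at 0.20 among them) and 1 lower. With fry the ribosomal list passed (fry adjusted p = 0.00932), as did the 3 SoxC genes (fry adjusted p = 2.81e-05). The SoxC list holds Sox11, the targeted gene, while Sox4 and Sox12 did not pass, so its result restates the knockout. Small nucleolar RNAs rose by a median of 0.09, with 39 of 51 above 0 (camera adjusted p = 0.00650), and had an adjusted p of 0.686 with an estimated correlation. Snord73b rose by 0.57 (SE 0.11, limma adjusted p = 0.0384), and 5 were higher adjusted over the list alone, among them Snora73b (0.59) and Snord47 (0.67). This list had a camera adjusted p of 0.211 without wild type replicate 3 and 0.108 without knockout replicate 2. Snord73b was lost without each array but wild type replicates 1 and 4 (limma adjusted p up to 0.108), while Snora73b passed without knockout replicate 1 (0.0223) and Snord47 without wild type replicate 1 (0.0290). On all arrays, Snord73b was lost with the replicate block, the Y-linked covariate, no moderation and every probe set tested (limma adjusted p = 0.0908, 0.0664, 0.139 and 0.0580), while Snora73b passed with the block (0.0291) and Snord47 with the covariate (0.0336). Histone genes had a camera adjusted p of 0.317, and 0.0303 with genes above the median level. The embryo sex genes, with Xist at -1.83, Eif2s3y at 1.11 and Kdm5d at 1.02, had limma adjusted p-values between 0.698 and 0.726 and a camera adjusted p of 0.751.

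Genes close to Sox11 differed between genotypes more often than other genes. Within 10 Mb of Sox11, 25 of 82 measured genes (30.5%) had an unadjusted limma p under 0.05, against 3191 of 19202 other genes (16.6%), an odds ratio of 2.20 (Fisher's exact test, two-sided p = 0.00166). Past the adjusted threshold were 7 of the 82. Rrm2 (-0.77) and Meox2 (-0.50) were named by the rule, and Alkal2 (0.61), Rnf144a (-0.36), Asap2 (-0.34) and the predicted genes Gm5784 (-0.68) and Gm9866 (0.74) were chosen after their values were seen. Rnf144a and Asap2 missed the threshold without each array but wild type replicate 1 (limma adjusted p up to 0.112 and 0.132), and Gm5784 without wild type replicates 1 and 3 and each knockout array (up to 0.0778), and all 3 also with the Y-linked signal as a covariate and without moderation. Rnf144a and Asap2 were also lost with the replicate block, a further quantile normalization and every probe set tested, and Gm9866 and Meox2 without moderation. The percentage was 28.6% within 5 Mb (Fisher's exact p = 0.0582) and 26.1% within 20 Mb (Fisher's exact p = 0.00504), and within 10 Mb it was 21.95% without knockout replicate 1, 3 or 4 (Fisher's exact p = 0.0205, 0.0916 and 0.0166). An odds ratio of at least 2.20 came up in 6 of the 35 splits of the arrays.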

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

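Each of 228 groups of 4 arrays, over the named genes and the list means, was searched for 1 array far from the other 3, and 15 had such an array, where chance gives about 1 in 20. No test in this part was chosen after the result was seen, and no explanation was tested for these values.

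In wild type replicate 1 the Y-linked genes Eif2s3y and Kdm5d stood at 10.29 and 9.90 and Xist at 5.200, against 5.28 to 5.37, 5.42 to 5.71 and 12.63 to 12.85 in the other wild type arrays. The same array was lowest for Foxd1 at 9.94, against 10.31 to 10.37, and for Gata3 at 9.99, against 10.07 to 10.09. It was also lowest for Cbx2 at 10.68, against 10.752 to 10.765, and for Tead2 at 11.96, against 12.01 to 12.02.

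Wild type replicate 2 was highest for Ccn1 at 9.51, against 9.22 to 9.26, and for Slco5a1 at 7.68, against 7.31 to 7.36. It was lowest for Cntn1 at 6.69, against 7.13 to 7.17, and for Sall1 at 8.67, against 8.88 to 8.90. In wild type replicate 3 Rhag stood at 7.38, against 6.78 to 6.87. Among the knockout arrays Meox2 stood at 9.34 in replicate 3, against 9.09 to 9.10. The mean of the BMP targets was 9.05 in knockout replicate 3, against 9.18 to 9.20, and that of the stromal genes was 10.48 in knockout replicate 2, against 10.62 to 10.63.

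Of 6375 probe sets without a single gene symbol, which entered no comparison of genes, 20 passed limma's test over all 27478 probe sets at an adjusted p under 0.05. Of these 15 were lower and 5 higher in knockout, 16 had no symbol in the annotation used here and 4 had several.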

How the results depend on the processing

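No alternative was added after the data were seen. Sox11 stayed past the threshold under all 19 alternatives, from -2.73 to -2.63 (limma adjusted p up to 4.36e-04), and all 279 genes past the threshold kept their sign wherever they were tested. The count of 279 rose to 683 at an adjusted p under 0.1 and was 132 at an unadjusted p under 0.01 with at least 1.5-fold. Without moderation it was 55 (7 higher, 48 lower). With the Y-linked signal as a covariate it was 151 (34 higher, 117 lower), and a test of every probe set called 41 higher. When 1 array was left out the counts ran from 107 to 243 (17 to 55 higher, 88 to 192 lower), with fewer samples in each fit. Lower genes made up 74.9% of the calls, 73.1% after a further quantile normalization and 76.5% after median centring. A filter at the median of level left 349 calls and a filter at the 25th percentile 340, with fewer genes tested.

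With the replicate number as a block 166 genes passed (117 lower), and 140 of them were among the 279. Same-numbered arrays deviated from their genotype means with correlations from -0.165 to 0.0897, and 2 of 8 arrays correlated best with their own number. No pairing by number was seen in this way, but a shared litter or day is not excluded.

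Of the 40 lists 8 passed camera, and 7 to 10 when 1 array was left out. The same 8 passed on ranks with the preset correlation, 0 passed with an estimated correlation and 2 with fry. Those 2 include the SoxC list, which holds the targeted gene itself. Genes near Sox11 had 28.6% within 5 Mb, and from 21.95% to 31.7% when 1 array was left out. Over the 74 named genes besides Sox11, 1157 of 1384 comparisons were the same, 171 lost and 45 gained a call. Of 34 called named genes 8 passed under every alternative that tested them (Sox11, Aldh1a3, Car14, Cbx2, Dpysl5, Pcdhb18, Rrm2 and Slco5a1), and 15 of 41 others passed under at least 1. The sign reversed 11 times, in genes far from the threshold. Leaving out 1 array, Bmp4 ran from -0.0319 to 0.168, Gdnf from -0.133 to 0.00792 and Grem1 from -5.8e-04 to 0.334, each reversed without wild type replicate 4. Robo2 ran from -0.0673 to 0.0296 (reversed without wild type replicate 1 and knockout replicate 1), Sox12 from -0.0162 to 0.0583 (wild type replicate 4 and knockout replicate 3) and Wnt11 from -0.0134 to 0.0425 (wild type replicate 3 and knockout replicates 2 and 3). With array weights Sox12 was -0.00175. Over lists 637 of 677 comparisons were the same, 25 lost and 14 gained a call, and 57 uncalled ones changed direction. Somite genes reversed to lower at a camera adjusted p of 7.01e-04 with genes above the median level, where fewer genes were tested. Apart from fits on fewer samples or genes, the cause was not tested. Genes near the lower end of signal, such as Hamp at 5.76 in wild type, limit what a small change can show.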

Other observations

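Apart from Dpysl5, which the rule named, the genes of the next 2 paragraphs were chosen after their values were seen. Of the tests weighed further on, those of the odds ratio near Sox11 over the splits, linked alleles, neural cells, duct epithelium (both) and gut endoderm were chosen only after the result was seen.

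Among genes outside the lists, 3 of the 5 collapsin response mediator genes, which act on the cytoskeleton of growing neurites, fell in the knockout ridges. Dpysl5 was at -1.20, Dpysl4 at -1.04 (limma adjusted p = 0.0148) and Crmp1 at -0.71 (limma adjusted p = 0.00700), whereas Dpysl2 at -0.07 and Dpysl3 at -0.12 did not pass (limma adjusted p = 0.632 and 0.656). Syt5, a synaptotagmin of secretory vesicles, fell by 1.14 on the log2 scale, Sema6c, a transmembrane semaphorin, by 1.03, Astn1, which acts in neuronal migration, by 0.93, and Rtn1, a reticulon of neurons, by 0.81. These 4 genes, the vesicle gene Nsg1 (-0.95), the adaptor gene Apba2 (-0.91) and the glypican gene Gpc2 (-0.73) passed under every alternative that tested them. Tubb2b (-0.62) and Dpysl4 missed the threshold without wild type replicate 2 (limma adjusted p = 0.0548 and 0.0518), and both were lost with the replicate block and without moderation. The list of neurons fixed in advance had a median of -0.02, with 12 genes below and 12 above 0. Of its 7 genes above the median level of all genes, 6 lay below 0, with a median of -0.355 over the 7. Common neuronal genes such as Elavl3 (-0.21), Nefl (-0.39) and Gap43 (-0.10) lay below 0 but did not pass (limma adjusted p = 0.581, 0.461 and 0.588).

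Further genes outside the lists changed in either direction. The tight junction gene Cldn8 rose by 0.71 (limma adjusted p = 0.00648), the membrane protease gene Dpp4 by 0.62 (limma adjusted p = 0.00319), the protease inhibitor gene Spint1 by 0.54 (limma adjusted p = 0.0273) and Pkhd1, the gene of autosomal recessive polycystic kidney disease, by 0.46 (limma adjusted p = 0.0150). Prom1, which marks the apical membrane, fell by 0.94 on the log2 scale, and Slc2a4, the insulin-responsive glucose transporter, by 0.95 (limma adjusted p = 3.98e-04 for both). Dpp4, Prom1 and Slc2a4 passed under every alternative that tested them, and Cldn8, like Crmp1 above, under all but the model without moderation. Spint1 missed the threshold without wild type replicate 2 and without each knockout array (limma adjusted p up to 0.0881), with the Y-linked signal as a covariate and without moderation. Pkhd1 missed it without wild type replicate 2 or knockout replicate 4 (limma adjusted p up to 0.0565), with the replicate block and without moderation.

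Chance in the grouping of the arrays was tested over the 35 splits of the 8 arrays into 4 and 4. For genes past the threshold it is argued against: only 1 split, the real one, gave as many as 279, and the highest other gave 7. A count of 1 is the lowest that 35 splits can give. A difference other than Sox11 that falls along the genotypes is not tested by the splits. The same holds for the 70 higher and 209 lower genes, each reached in 1 split, where no other split gave more than 5 in 1 direction. For the gene lists it cannot be excluded: 12 of the 35 splits gave at least 8 lists past camera's threshold, and the highest other gave 13.

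Genes within 10 Mb of Sox11, Rrm2 and Meox2 among them, changed more often than others, but chance in how the arrays fell cannot be excluded, since 6 of 35 splits gave an odds ratio of at least 2.20 and the highest other gave 3.36. The percentage alone was highest in the real split (30.5%, highest other 17.1%), but so was that of other genes (16.6%, highest other 10.2%), and the difference was 13.9 points against at most 11.3. Most of the other splits with such an odds ratio held unequal numbers of wild type and knockout arrays on each side, so part of the genotype difference remained in them. Local clusters of changed genes are argued against only in part. Of 19118 windows around other genes, 0.262% held as large a percentage, and the highest held 36%. These windows overlap and include those around Sox11's own neighbours, so they are not independent of each other or of the pattern. An open explanation is that the knockout embryos carried linked alleles of the strain in which the mutation was made, on a mixed background, which may change transcripts or probe binding near Sox11, but the comparison with other genes (Fisher's exact p = 0.00166) is the pattern itself and lends this no support. Without knockout replicate 1, 3 or 4 the percentage was 21.95% (Fisher's exact p = 0.0205, 0.0916 and 0.0166), and a direct effect of Sox11 on its neighbours was not tested.

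Of 21 protocadherin beta genes 12 fell and 9 did not pass. Fewer neural cells in the knockout dissections stay open. The 24 neural genes had a median of -0.02 (95% bootstrap interval -0.14 to 0.07) against -0.68 in the family. But the 7 of them above the median level of all genes, where no member of the family lies, had a median of -0.355, with 6 below 0. Their difference from the family lay between -0.11 and 1.02 (95% bootstrap interval). Both intervals resampled genes as if independent, not arrays, so they do not measure the spread between replicates. A strain haplotype around the cluster cannot be told apart from other causes, as 16.8% of 95 neighbours within 5 Mb had an unadjusted p under 0.05 against 16.6% of other genes (Fisher's exact p = 0.891), which a change of the cluster alone would also give. Signal shared between similar members stays open too, because their deviations within genotypes correlated at a mean of 0.298, above the 95th percentile of 0.0902 of 1000 random lists, as co-regulated genes would do as well. A lower output of the whole cluster without Sox11 may thus be a hypothesis, but it was not tested.

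Nephric duct genes lay higher in the knockout, and gut endoderm carried into the dissections stays open, since only 2 of 11 gut genes outside the list lay above the median level of all genes (median change 0.0701), too few to decide, while all 11 had a median of 0.0244 (95% bootstrap interval -0.02 to 0.08) against 0.16 in the duct list. A larger share of duct epithelium stays open too. Of 12 epithelial markers, all of them members of the duct list, 11 lay above 0. In the whole list 21 of 27 genes lay above 0 and 6 below, so the markers rose more uniformly than the list. The changes of the 12 markers, from -0.07 for Hoxb7 to 0.63 for Calb1, differed by more than their errors (Cochran's Q, n = 12 markers, p = 4.87e-05). However, markers also expressed outside the duct would rise less. Without Hoxb7 p was 0.0205 (n = 11 markers). Without Hoxb7 and Ret, left out after their values were seen, the pooled change was 0.23 (SE 0.03) and p was 0.0737 (Cochran's Q, n = 10 markers), which decides nothing by itself. All markers were read on the same 8 arrays. The pooled SE and Cochran's Q treat them as independent, so they do not measure the spread between replicates. The same holds for the bootstrap interval of the gut genes, which resampled genes and not arrays. Chance in the rise of the duct list itself is not excluded. The splits, of which 12 of 35 gave at least 8 lists, only counted lists and did not follow this one.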
